A study of Mus musculus with 15 samples.

How the data were processed

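Gene expression was measured in 15 mouse samples, 1 array each, from total RNA extracted with Trizol and labelled with biotin for hybridisation to Affymetrix whole-transcript arrays. The values analysed were those deposited by the authors, 1 column per array, in log2 units. The log base is not written in the table and was inferred from the values, which ran from 0.850 to 14.6 with no value below 0, the range that base-2 logs of scanner intensities take. Per the submitters' processing notes the values came from Affymetrix Power Tools, with no version given. The background correction, the normalization between arrays, the summarization of probes and the genome build are not given in the sources used here. Array medians lay between 5.94 and 6.12, close but not identical, and probe sets were not centred on their own means. No values were transformed or normalized again for the reported results.

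The table held 35556 probe sets, of which 23410 stood in the gene table of the platform. Probe sets with a single gene symbol (21789) were kept, 21698 of them matched by gene ID to a current table, which changed 0 symbols. The 1621 probe sets with several symbols and the 12146 without an entry were left out of the gene results, because no single gene could be named for them. Where several probe sets carried the same symbol (999 genes) the one with the highest mean over all arrays was used, which gave 19938 genes, with no filter on dim genes. As a rough level of background, the 95th percentile of 1027 olfactory receptor genes (5.43) was chosen after the values were seen. Of the genes that passed, 256 at 5 weeks (6.59%) and 266 at 16 weeks (4.3%) had both groups at or below that level. For the interaction this held for 157 genes (4.31%), for age in WT 465 (7.54%) and for age in OBOB 308 (4.89%), over the groups each compares.

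Arrays were grouped by genotype and time point as labelled. A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes) under R 4.3.3, with statmod 1.5.0 for the rotation tests. Contrasts were OBOB minus WT at 5 weeks, OBOB minus WT at 16 weeks, the difference of these effects (16 minus 5 weeks), and 16 minus 5 weeks within each genotype. Tests were two-sided moderated tests, p-values were adjusted by Benjamini-Hochberg over 19938 genes, and a gene passed below the 5% level. Standard errors are those of the moderated model. The number of arrays limits the precision, and replicate numbers were not treated as pairs because the labels do not say that they mark shared animals or days.

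On simulated data with the same group sizes and 50 changed genes per size among 19938, log2 changes of 2 were recovered in 100% of genes in every comparison. A change of 1 was recovered in 100% except for the interaction (96%). A change of 0.5 was recovered in 80% for the genotype effect at 5 weeks, 84% at 16 weeks, 54% for the interaction, 86% for age in WT and 84% for age in OBOB. For a change of -0.5 these shares were 92%, 78%, 46%, 84% and 88%. Among unchanged genes 16, 6, 5, 9 and 6 passed in the same order.

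There were 46 gene lists of 934 genes, 846 of them measured, for macrophage states, lipid and energy metabolism, stress responses and cell types. They were tested against all other genes with camera at a preset correlation of 0.01, with an estimated correlation per list beside it. Beside these, fry, a rotation test, asked whether the genes of a list moved on balance in 1 direction, without comparing them with other genes. Adjustment was over the 46 lists of a comparison. Some genes stand in more than 1 list, as in the fibroblast and matrix lists or the lipid-associated and lysosomal lists, so these are not independent results. Gene counts are also given adjusted over the list alone. The lists, tests, alternatives and the rule for naming genes were chosen before the data were examined. That rule named the 8 largest rises and the 8 largest falls of each genotype effect among genes that passed and whose arrays did not overlap between the groups, and 5 of each for the other comparisons, without the overlap condition for the interaction. It also allowed up to 3 members per list that passed for genotype effects and up to 2 for the others, and 25 index genes whatever their result. Predicted genes and olfactory, vomeronasal and taste receptors were left out of the largest changes. Genes of further lists, for epididymis, eosinophils and basophils, were written down after a pattern was seen.

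Alternatives tried were quantile normalization, centring each array on its median, removing the third of genes with the lowest means, the mean of all probe sets of a gene, eBayes with a trend and robust moderation, array weights, the replicate number as a block within each time point, only the compared groups in the fit, a minimum log2 change of 1, fry, the estimated correlation, and leaving out each array in turn. Covariates for stromal markers and for epididymis genes were added after seeing the data.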

Results

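Gene expression was measured on whole-transcript Affymetrix arrays hybridised with total RNA from mouse adipose tissue macrophages and adipocytes, which the labels name together for every array without saying which of these cells each array holds. The design crossed 2 genotypes, WT and OBOB (read here as ob/ob, the mutation that leaves mice without functional leptin and makes them obese), with 2 time points, 5 and 16 weeks. There were 4 arrays of WT at 5 weeks, 3 of OBOB at 5 weeks, 4 of WT at 16 weeks and 4 of OBOB at 16 weeks, 15 in all. The study's title asks how lipid is shared between adipocytes and tissue macrophages in obese mice and how this bears on M2 and M1 macrophage polarization. Each comparison of genotypes at 1 time point therefore asks which macrophage, lipid and adipocyte genes differed in obese mice. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these arrays, and the number of arrays limits the precision. The labels do not say whether the arrays of the 2 time points were processed together. Their description codes run in separate ranges for 5 and 16 weeks and skip a number within OBOB at 5 weeks. A difference between 5 and 16 weeks may therefore coincide with a batch. Genotypes were compared within a time point.

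Macrophage and adipocyte transcripts were both read, on probe sets whose levels cannot be compared with each other. Cd68, a lysosomal glycoprotein of macrophages, lay at 12.11 ± 0.07 (SD, n = 4) in WT and 12.25 ± 0.13 (SD, n = 3) in OBOB at 5 weeks on the log2 scale. Adipoq, the adipocyte hormone adiponectin, lay at 7.17 ± 0.04 (SD, n = 4) and 7.38 ± 0.69 (SD, n = 3) in the same groups. Lep itself lay at 5.43 ± 0.18 (SD, n = 4) in WT at 5 weeks, equal to the 95th percentile of olfactory receptor genes (5.43), and at 6.10 ± 0.18 (SD, n = 3) in OBOB. The ob mutation leaves a transcript, so the Lep level does not check the genotype labels. The 15 arrays fell into the 4 labelled groups: every pair of arrays within a group correlated at 0.9835 or more across all probe sets, and the highest correlation between arrays of different groups was 0.982. The first principal component held 38% of the variance and ordered WT at 5 weeks, WT at 16 weeks, OBOB at 5 weeks and OBOB at 16 weeks.

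**Figure D1:**
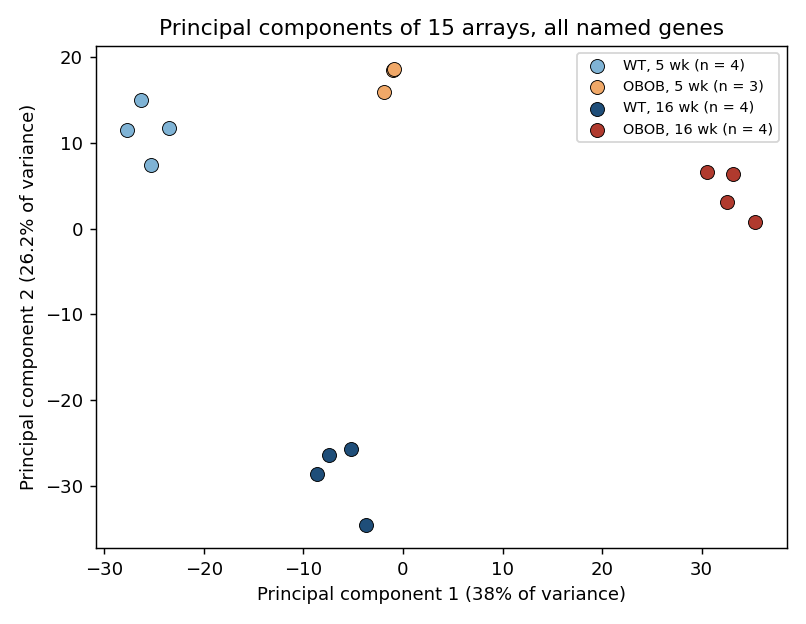
Principal components 1 (38% of variance, x axis) and 2 (26.2% of variance, y axis) of the 15 arrays over 19938 genes, 1 point per array, coloured by group. The arrays of each group sit together and apart from the other groups.

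At 5 weeks, the largest rises in OBOB included genes of lipid handling and of the vacuolar proton pump. Gpnmb, a glycoprotein of phagocytes with lipid-filled lysosomes, rose from 7.54 ± 0.35 (SD, n = 4) in WT to 11.51 ± 0.15 (SD, n = 3) in OBOB, 15.7-fold (log2 difference 3.97 ± 0.16 SE, adjusted p = 9.97e-11). Tm4sf19, a tetraspanin-like membrane protein, rose 11.3-fold and Atp6v0d2, a subunit of the vacuolar proton pump, 9.83-fold. Lpl, the lipase that frees fatty acids from lipoproteins, rose from 10.72 ± 0.09 (SD, n = 4) to 12.38 ± 0.05 (SD, n = 3), 3.17-fold. The matrix glycoprotein Thbs1 rose 6.94-fold, the metalloproteinase Adam8 6.38-fold and the arginine-degrading enzyme Arg1 6.62-fold, from 6.15 ± 0.13 (SD, n = 4) to 8.88 ± 0.17 (SD, n = 3). Among genes whose arrays did not overlap between the groups, Pla2g2d, a phospholipase, fell most, 6.04-fold from 10.43 ± 0.19 (SD, n = 4) to 7.84 ± 0.39 (SD, n = 3). Next came the sulfotransferase Sult1e1 (4.78-fold), the chemokine receptor Cx3cr1 (4.12-fold) and the nucleotide receptor P2ry13 (3.97-fold). The iron exporter Slc40a1, Fcrls, Inmt and the prostaglandin-degrading enzyme Hpgd fell 3.82-fold, 3.81-fold, 3.75-fold and 3.48-fold. Adjusted p for these falls lay between 1.11e-08 and 9.2e-05. Gpx5, Spag11b and Adam7, genes of the epididymis, also passed as lower, but their arrays overlapped between the groups. Their log2 differences were -3.00 (adjusted p = 0.0306), -2.35 (adjusted p = 0.0193) and -1.95 (adjusted p = 0.0413), that of Gpx5 larger than for Pla2g2d.

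Of the 26 alternative (M2) macrophage markers, 18 fell and 5 rose at 5 weeks, with a median log2 difference of -0.63. The scavenger receptor Cd163 fell 2.06-fold, the mannose receptor Mrc1 1.78-fold, the lectin Clec10a 1.66-fold, the phosphatidylserine receptor Timd4 3.31-fold and the chemokine Ccl24 3.04-fold. Arg1 went the other way, and Retnla did not pass (log2 difference -0.17 ± 0.12 SE, adjusted p = 0.339). Adjusted over the list alone, 18 members were lower and 6 higher. The list's fall passed at adjusted p = 6.72e-06 with the preset correlation, and adjusted p = 0.27 with an estimated correlation. Of 23 classical (M1) markers, 8 rose, 6 fell and 9 did not pass, and adjusted over the list alone 9 were higher and 7 lower. Their median was 0.13 and the list did not pass (adjusted p = 0.126, and adjusted p = 0.5 with an estimated correlation). Within it the cytokine Tnf rose 2.62-fold, from 9.09 ± 0.10 (SD, n = 4) to 10.48 ± 0.01 (SD, n = 3), the prostaglandin synthase Ptgs2 3.14-fold, Il1a 2.30-fold, Il6 2.23-fold, the integrin Itgax (CD11c) 2.11-fold and Il1b 1.63-fold. Il6 in WT lay at 5.39, below the olfactory receptor level, so its fold is a lower bound. Nos2 (log2 difference 0.13 ± 0.09 SE, adjusted p = 0.376) and Ccl2 (-0.33 ± 0.12 SE, adjusted p = 0.0707) did not pass. Ccl2 passed as lower without WT replicate 1 (-0.41) or OBOB replicate 1 (-0.41) and without the dimmest genes (-0.33), its adjusted p ranging from 0.0262 to 0.283 over the settings fixed in advance.

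**Figure D2:**
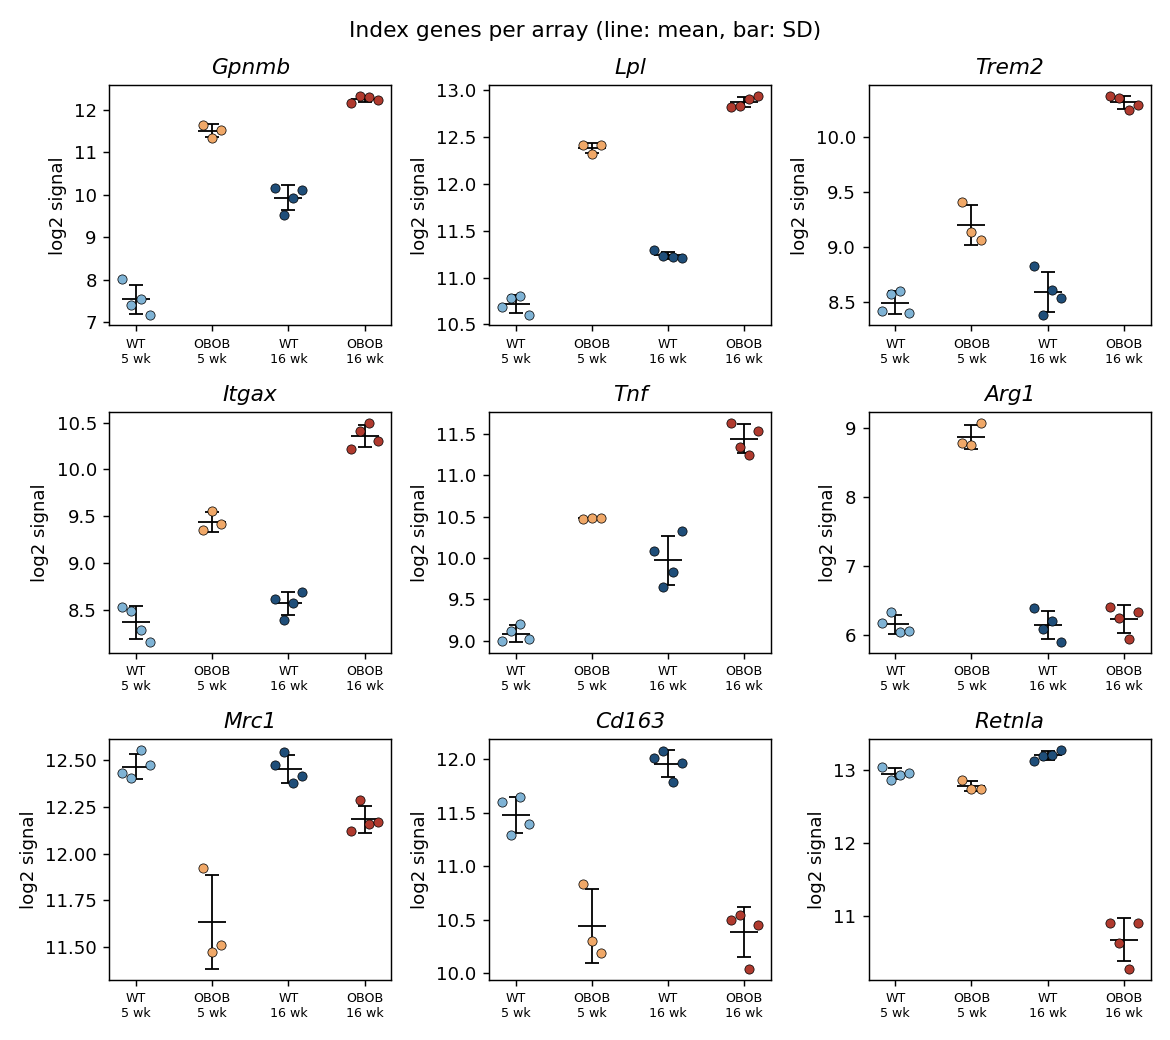
Log2 signal (y axes) of 9 genes in each of the 15 arrays by group, with the group mean (line) and SD (bar). Gpnmb, Lpl, Trem2, Itgax and Tnf lie higher in OBOB at both time points, Arg1 at 5 weeks, and Retnla falls from 13.19 in WT to 10.68 in OBOB at 16 weeks.

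Genes of lipid-associated macrophages, a state described around dying adipocytes, rose together at 5 weeks: 23 of 25 were higher, none was lower, and the median log2 difference was 1.13 (adjusted p = 2.63e-33, and adjusted p = 0.016 with an estimated correlation). Adjusted over the list alone the count was also 23. Besides Gpnmb, Atp6v0d2 and Lpl these included the elastase Mmp12 (5.24-fold), the fatty acid binding protein Fabp5 (2.65-fold) and the lipid receptor Trem2 (1.63-fold). Of 18 genes of fatty acid uptake and binding 11 rose and none fell (11 higher adjusted over the list alone; adjusted p = 2.16e-08, and adjusted p = 0.016 with an estimated correlation), among them the oxidised-lipoprotein receptor Olr1 (4.81-fold) and Cd36 (1.34-fold). Of 30 lysosomal and proton pump genes 17 rose and 3 fell (19 and 5 adjusted over the list alone), with the proteases Ctsk 6.02-fold and Ctsl 2.67-fold higher (adjusted p = 3.42e-10 for the list, but adjusted p = 0.17 with an estimated correlation). Among 18 lipid droplet proteins 8 rose and none fell, led by Hilpda (4.28-fold) and Plin2 (1.79-fold), with 8 higher adjusted over the list alone (adjusted p = 2.72e-05, and adjusted p = 0.058 with an estimated correlation). The cholesterol exporter Abca1 fell 1.33-fold.

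Lists of glycolysis, cholesterol synthesis, oxidative stress and hypoxia also rose at 5 weeks. That of the unfolded protein response did not pass (5 higher and 3 lower of 27, also adjusted over the list alone; adjusted p = 0.198). Of 19 glycolysis genes 10 were higher and none lower (11 adjusted over the list alone; adjusted p = 1.79e-09, and adjusted p = 0.029 with an estimated correlation), including the lactate transporter Slc16a3 (3.98-fold) and the glucose transporter Slc2a1 (2.24-fold). Of 21 cholesterol synthesis genes 13 were higher and none lower (15 and 1 adjusted over the list alone; adjusted p = 5.34e-09, and adjusted p = 0.034 with an estimated correlation), with Idi1 1.81-fold and Msmo1 1.76-fold higher. NRF2 and oxidative stress genes counted 15 higher and 1 lower of 25, with the cystine transporter Slc7a11 4.38-fold and Srxn1 3.05-fold higher (16 and 1 adjusted over the list alone; adjusted p = 3.35e-10, and adjusted p = 0.055 with an estimated correlation). Hypoxia response genes counted 10 higher and 1 lower of 20, as they did adjusted over the list alone, with Vegfa 3.43-fold higher (adjusted p = 9.07e-07, and adjusted p = 0.057 with an estimated correlation). Interferon-stimulated genes fell: 19 of 23 were lower and none higher (22 lower adjusted over the list alone), with Ifit3 2.72-fold and Rtp4 2.28-fold lower (median -0.65, adjusted p = 1.55e-15, and adjusted p = 0.055 with an estimated correlation). The immediate early and dissociation response list, of genes that respond to tissue handling, also passed as lower in OBOB at 5 weeks. Its mean level was 10.245 ± 0.024 (SD, n = 3) against 10.375 ± 0.038 (SD, n = 4) in WT. That call was lost with an estimated correlation, with the replicate block and without WT replicates 2, 3 or 4 or OBOB replicates 1 or 3. Its adjusted p ranged from 0.0039 to 0.101 over the settings fixed in advance other than that correlation.

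Markers of several cell types moved with genotype at 5 weeks. Of 19 core macrophage and monocyte markers 13 fell and 1 rose (14 and 1 adjusted over the list alone), with Aif1 2.47-fold lower (median -0.59, adjusted p = 2.96e-07, and adjusted p = 0.16 with an estimated correlation), whereas the integrin Itgam rose 1.25-fold. Monocyte and recruited macrophage markers counted 6 higher and none lower of 13, with the lectin Clec4e 5.48-fold and coagulation factor F10 4.64-fold higher (7 adjusted over the list alone; adjusted p = 1.34e-06, and adjusted p = 0.032 with an estimated correlation). Of 18 fibroblast markers 14 rose and none fell (adjusted p = 3.05e-11, and adjusted p = 0.11 with an estimated correlation; 14 adjusted over the list alone), with the proteoglycan Lum 2.90-fold higher. Matrix genes, which share Lum and several collagens with the fibroblast list, moved beside them: 27 of 31 rose and 1 fell (27 and 2 adjusted over the list alone), with Mmp19 6.17-fold higher (adjusted p = 4.58e-23, and adjusted p = 0.055 with an estimated correlation). Of 9 eosinophil markers 7 rose and none fell (7 adjusted over the list alone; median 1.47, adjusted p = 1.29e-08, and adjusted p = 0.061 with an estimated correlation), among them the chemokine receptor Ccr3 (5.22-fold) and the lipoxygenase Alox15 (4.71-fold). Of 16 mast cell markers 10 rose and none fell (10 adjusted over the list alone), with the carboxypeptidase Cpa3 5.04-fold and Mcpt4 3.49-fold higher (adjusted p = 3.26e-07, and adjusted p = 0.12 with an estimated correlation). T and NK cell markers fell in 15 of 30 and rose in 1 (17 and 1 adjusted over the list alone), with Gzma 2.78-fold and Nkg7 2.55-fold lower (adjusted p = 1.04e-07, and adjusted p = 0.057 with an estimated correlation). Rnase2a, of the eosinophil-associated ribonuclease family, rose 6.54-fold and Retnlg, expressed by neutrophils, 6.70-fold. Members of the former family are near copies of each other, so the probes may not tell Rnase2a from its relatives.

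Adipocyte markers rose in 8 of 20 genes at 5 weeks and fell in none, the same count as adjusted over the list alone (median 0.21, adjusted p = 3.81e-05, and adjusted p = 0.11 with an estimated correlation). Pparg, the adipogenic receptor, rose 1.60-fold and Lep 1.59-fold, a lower bound because Lep in WT was at the olfactory receptor level. Adipoq did not pass (log2 difference 0.21 ± 0.21 SE, adjusted p = 0.548), but passed at 0.61 (adjusted p = 0.00178) without OBOB at 5 weeks replicate 1, its adjusted p ranging from 0.00178 to 0.998 over the settings fixed in advance. The leptin receptor Lepr did not pass (log2 difference -0.14 ± 0.12 SE, adjusted p = 0.461). It lay below the olfactory receptor level in both groups, so a difference in it was not measurable. In all, 3887 of 19938 genes passed at the 5% level (19.5%), 2023 higher and 1864 lower in OBOB, of which 266 differed at least 2-fold (188 higher and 78 lower). With each array centred on its median the split was 2384 higher and 1234 lower, so the balance of directions depends on the scaling. With the mean of endothelial, fibroblast, mesothelial and mural markers as a covariate, chosen after seeing the data, 2246 genes passed, of which 2028 were among the 3887, and Itgam (0.30) and Abca1 (-0.36) were no longer called. With it the classical (M1) list passed as higher at a median of 0.17. With the mean of epididymis genes as a covariate, also chosen after seeing the data, 2820 genes passed, 2592 of them among the 3887.

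At 16 weeks, Tm4sf19 rose 9.24-fold in OBOB, from 7.72 ± 0.23 (SD, n = 4) to 10.93 ± 0.06 (SD, n = 4), the retinol dehydrogenase Dhrs9 7.84-fold, Atp6v0d2 7.10-fold, the serotonin receptor Htr2b 7.10-fold and the ubiquitin ligase Rnf128 7.08-fold. Adam8, the interleukin-7 receptor Il7r and Zranb3 rose 6.51-fold, 6.40-fold and 5.75-fold, and adjusted p for these rises lay between 1.94e-14 and 1.11e-10. Sult1e1, which inactivates oestrogens, fell 32-fold from 10.54 ± 0.37 (SD, n = 4) to 5.54 ± 0.24 (SD, n = 4), and Car3, an adipocyte carbonic anhydrase, 12-fold from 10.76 ± 0.06 (SD, n = 4) to 7.18 ± 0.09 (SD, n = 4). Inmt, Rnase2a, Pla2g2d and the opioid precursor Penk fell 9.79-fold, 9.28-fold, 9.04-fold and 8.79-fold. The gelatinase Mmp9 fell 7.81-fold and the cytochrome Cyp2e1 6.90-fold. The folds of Htr2b, Rnase2a and Cyp2e1 are lower bounds, since their lower group lay below the olfactory receptor level (5.43).

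Of the 26 alternative (M2) markers 20 fell and 3 rose at 16 weeks, the same count as adjusted over the list alone, with a median of -0.70 (adjusted p = 8.86e-11, but adjusted p = 0.21 with an estimated correlation). Retnla fell 5.72-fold, from 13.19 ± 0.06 (SD, n = 4) to 10.68 ± 0.30 (SD, n = 4), the lectins Cd209g and Cd209d 6.39-fold and 5.91-fold, Timd4 6.12-fold, Cd163 2.98-fold and Clec10a 1.64-fold. The anti-inflammatory cytokine Il10 rose 2.29-fold. Arg1 did not pass (log2 difference 0.09 ± 0.12 SE, adjusted p = 0.657). Mrc1 fell 1.20-fold (adjusted p = 0.0234), a call lost when any 1 of WT at 16 weeks replicates 1 or 2 or OBOB at 16 weeks replicates 1, 3 or 4 was left out (adjusted p from 0.0515 to 0.0692, and from 0.00571 to 0.0692 over all settings fixed in advance). It was also lost with each array centred on its median (-0.24, adjusted p = 0.0566). Of 23 classical (M1) markers 7 rose, 5 fell and 11 did not pass (7 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.542, and adjusted p = 0.81 with an estimated correlation), its median being -0.001 and its mean 0.16. Itgax rose 3.46-fold, from 8.57 ± 0.13 (SD, n = 4) to 10.36 ± 0.12 (SD, n = 4), Tnf 2.76-fold and Cxcl10 2.03-fold, whereas Nos2 fell 1.53-fold. Il1b (log2 difference 0.30 ± 0.14 SE), Il6 (-0.41 ± 0.15 SE) and Ccl2 (-0.08 ± 0.11 SE) did not pass, with adjusted p = 0.134, adjusted p = 0.0549 and adjusted p = 0.668. Il1b passed without WT replicate 1 (0.43) and with the replicate number as a block (0.30), its adjusted p ranging from 0.0196 to 0.338 over the settings fixed in advance. Il6 passed as lower without WT replicate 3 (-0.47) or OBOB replicate 4 (-0.55), with the replicate block (-0.41) and without the dimmest genes (-0.41), its adjusted p ranging from 0.00781 to 0.199.

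Lipid-associated macrophage genes rose in 23 of 25 and fell in 1 at 16 weeks, also adjusted over the list alone (median 1.38, adjusted p = 1.51e-21, but adjusted p = 0.07 with an estimated correlation). Gpnmb rose 5.01-fold, Slc37a2 3.99-fold, Trem2 3.31-fold, Lpl 3.11-fold, Plin2 2.00-fold and Cd36 1.25-fold. The mean level of the lipid droplet list, to which Plin2 also belongs, was 7.555 ± 0.011 (SD, n = 4) in OBOB and 7.600 ± 0.027 (SD, n = 4) in WT. That of the hypoxia list was 8.120 ± 0.053 (SD, n = 4) and 8.077 ± 0.052 (SD, n = 4). Lysosomal and proton pump genes rose in 29 of 30 and fell in none, also adjusted over the list alone, with Ctsk 4.65-fold and the galactosidase Gla 2.75-fold higher (median 0.65, adjusted p = 1.51e-21, but adjusted p = 0.12 with an estimated correlation). Cell cycle genes rose in 34 of 35 and fell in none (35 adjusted over the list alone; median 0.95, adjusted p = 2.27e-30, and adjusted p = 0.029 with an estimated correlation). The mitotic kinase Bub1 rose 3.62-fold, the spindle motor Kif11 3.36-fold and the topoisomerase Top2a 3.05-fold. Inflammasome and pattern recognition genes counted 14 higher and 3 lower of 26, with Tlr13 3.38-fold and the receptor antagonist Il1rn 5.09-fold higher (16 and 3 adjusted over the list alone; adjusted p = 0.000263, but adjusted p = 0.22 with an estimated correlation). Interferon-stimulated genes fell in 14 of 23 and rose in none, with Oas2 1.89-fold and Ifit3 1.73-fold lower (14 lower and 1 higher adjusted over the list alone; adjusted p = 3.28e-06, but adjusted p = 0.22 with an estimated correlation). The mean level of immediate early and dissociation response genes was 10.492 ± 0.017 (SD, n = 4) in OBOB and 10.631 ± 0.078 (SD, n = 4) in WT. Core macrophage markers as a list did not pass (adjusted p = 0.222), though Adgre1 (F4/80) rose 1.62-fold, Cd68 1.51-fold and Itgam 1.43-fold.

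**Figure D3:**
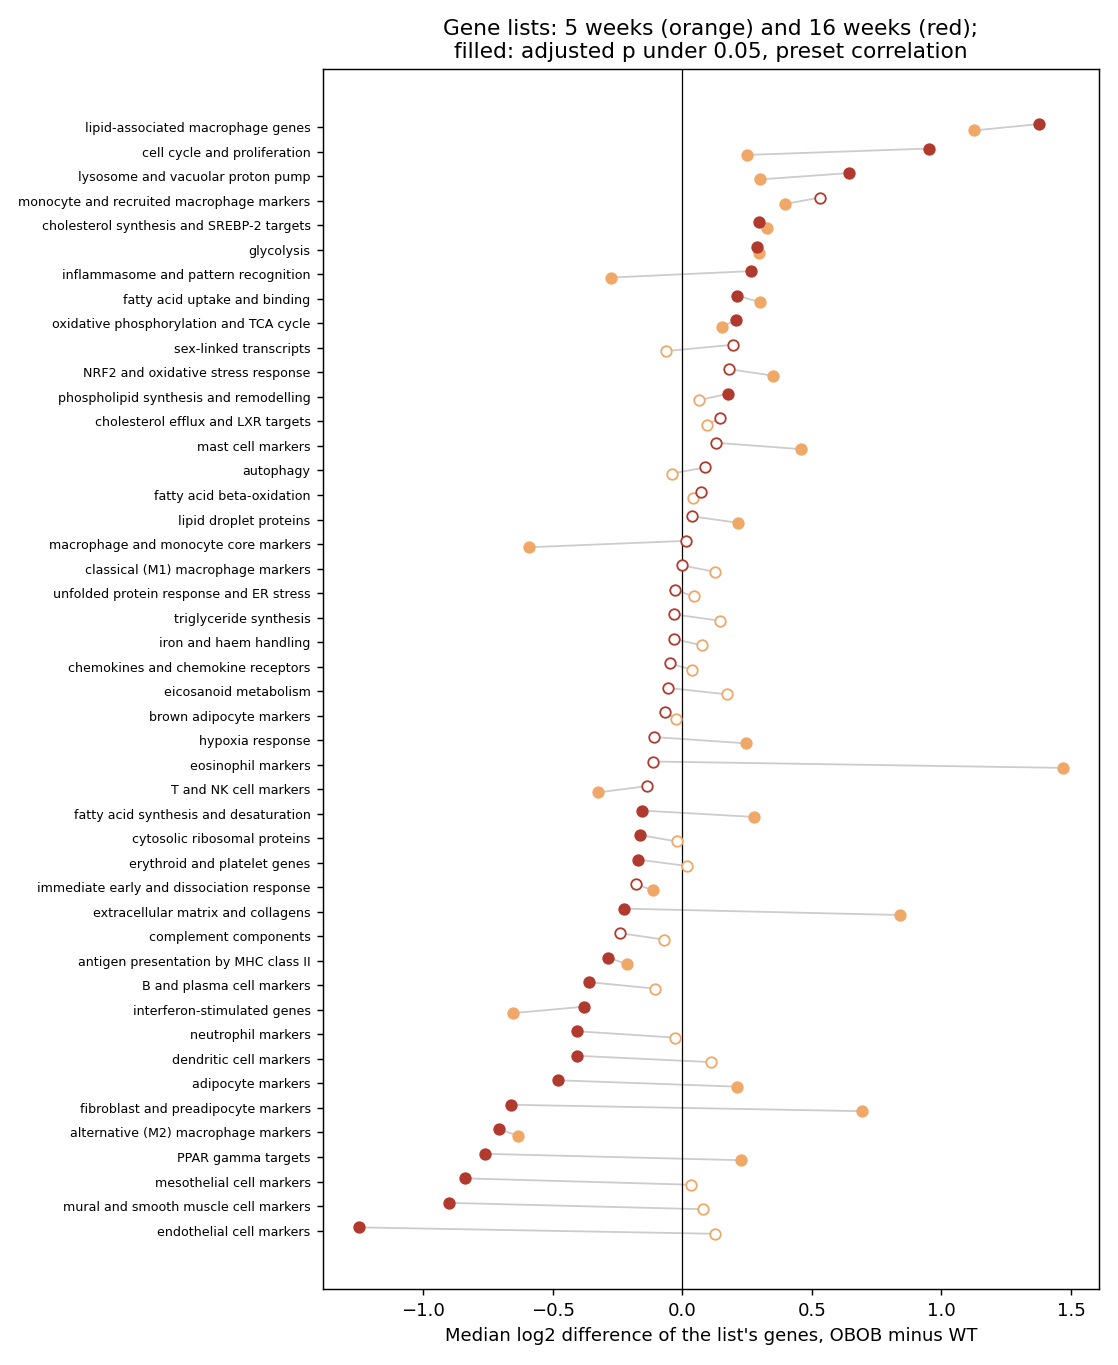
Median log2 difference, OBOB minus WT, of the measured genes of each of the 46 lists (x axis) at 5 weeks (orange) and 16 weeks (red), filled where the list passed with the preset correlation. Lipid-associated macrophage genes lie at 1.13 and 1.38, and endothelial markers at 0.13 and -1.25.

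Markers of non-immune cells fell in OBOB at 16 weeks. Endothelial markers fell in 19 of 20 genes and rose in none, also adjusted over the list alone, with the growth factor receptor Kdr 3.99-fold, Gpihbp1 3.41-fold and Rbp7 3.03-fold lower (median -1.25, adjusted p = 1.65e-16, but adjusted p = 0.21 with an estimated correlation). Mesothelial markers fell in 13 of 15 (14 lower and 1 higher adjusted over the list alone), with Upk3b 3.81-fold and Gpm6a 3.14-fold lower (adjusted p = 4.89e-09, but adjusted p = 0.12 with an estimated correlation). Mural and smooth muscle markers fell in 11 of 12 (12 adjusted over the list alone), with Myl9 2.53-fold and Rgs5 2.48-fold lower (adjusted p = 1.65e-07, but adjusted p = 0.21 with an estimated correlation). Fibroblast markers fell in 13 of 18 (14 lower and 1 higher adjusted over the list alone), with Clec3b 2.74-fold and Cd34 2.44-fold lower (adjusted p = 1.28e-07, but adjusted p = 0.22 with an estimated correlation). Adipocyte markers fell in 11 of 20 and rose in 2 (12 and 4 adjusted over the list alone), with Aqp7 3.93-fold and Adipoq at least 3.11-fold lower (to 4.87, below the olfactory receptor level), whereas Lep rose 1.38-fold (adjusted p = 6.23e-05 for the list, but adjusted p = 0.21 with an estimated correlation). Pparg also passed as higher, its arrays lying from 9.087 to 9.182 in OBOB and from 8.775 to 8.925 in WT. That call was lost with quantile normalization (0.17) and without WT replicate 1 (0.23) or OBOB replicates 2 (0.26) or 4 (0.25). The adjusted p of Pparg ranged from 0.0038 to 0.174 over the settings fixed in advance. The PPAR gamma targets, which share genes with the adipocyte list, fell in 11 of 16 and rose in 4, also adjusted over the list alone (adjusted p = 0.00236, but adjusted p = 0.25 with an estimated correlation). Among fatty acid synthesis genes 8 of 20 fell and 1 rose (8 and 2 adjusted over the list alone), with the desaturase Scd1 2.79-fold and Thrsp 2.33-fold lower (adjusted p = 0.00194, but adjusted p = 0.24 with an estimated correlation). At 5 weeks the mean level of this list had been higher in OBOB (7.805 ± 0.118 SD, n = 3) than in WT (7.530 ± 0.067 SD, n = 4). So had that of PPAR gamma targets (8.905 ± 0.155 SD, n = 3, against 8.685 ± 0.122 SD, n = 4).

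Markers of some other immune cells were lower too at 16 weeks. B and plasma cell markers fell in 12 of 19 and rose in 2 (14 and 2 adjusted over the list alone), with Bank1 3.78-fold lower (adjusted p = 7.53e-05, but adjusted p = 0.12 with an estimated correlation). Dendritic cell markers fell in 11 of 19 and rose in 1 (12 and 2 adjusted over the list alone), with Siglech 2.92-fold lower (adjusted p = 0.000323, but adjusted p = 0.21 with an estimated correlation). Neutrophil markers fell in 7 of 18 and rose in 1 (8 and 1 adjusted over the list alone), with S100a9 2.75-fold lower (adjusted p = 0.00276, but adjusted p = 0.35 with an estimated correlation). Eosinophil markers, which had risen at 5 weeks, did not pass (1 higher and 2 lower of 9, adjusted p = 0.542), nor did T and NK cell markers (adjusted p = 0.105) or mast cell markers (adjusted p = 0.459). In all, 6193 genes passed (31.1%), 3408 higher and 2785 lower, of which 619 differed at least 2-fold (283 higher and 336 lower). With the stromal marker mean as a covariate, chosen after seeing the data, 232 genes passed, 218 of them among the 6193. That covariate differed by -0.91 between the genotypes against a residual SD of 0.11, so it nearly repeats genotype. The median SE grew from 0.08 to 0.29 while the median absolute log2 difference of the 6193 genes went from 0.39 to 0.36. Calls that ended with it included Trem2 (1.37), Tnf (0.73), Plin2 (1.55), Cd163 (-1.73), Adipoq (-2.01) and Kdr (-0.68). With the estimated correlation the inflammasome list had already not passed at 16 weeks. Among lists its call ended with the covariate too, its median going from 0.26 to 0.07 (adjusted p = 0.968, against 6.33e-06 to 0.00408 over the settings fixed in advance other than that correlation). So did the calls of fibroblast (-0.27) and mesothelial markers (-0.21) and of PPAR gamma targets (-0.48). Kdr and the fibroblast and mesothelial markers belong to the covariate itself, so the end of their calls was largely built in.

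**Figure D4:**
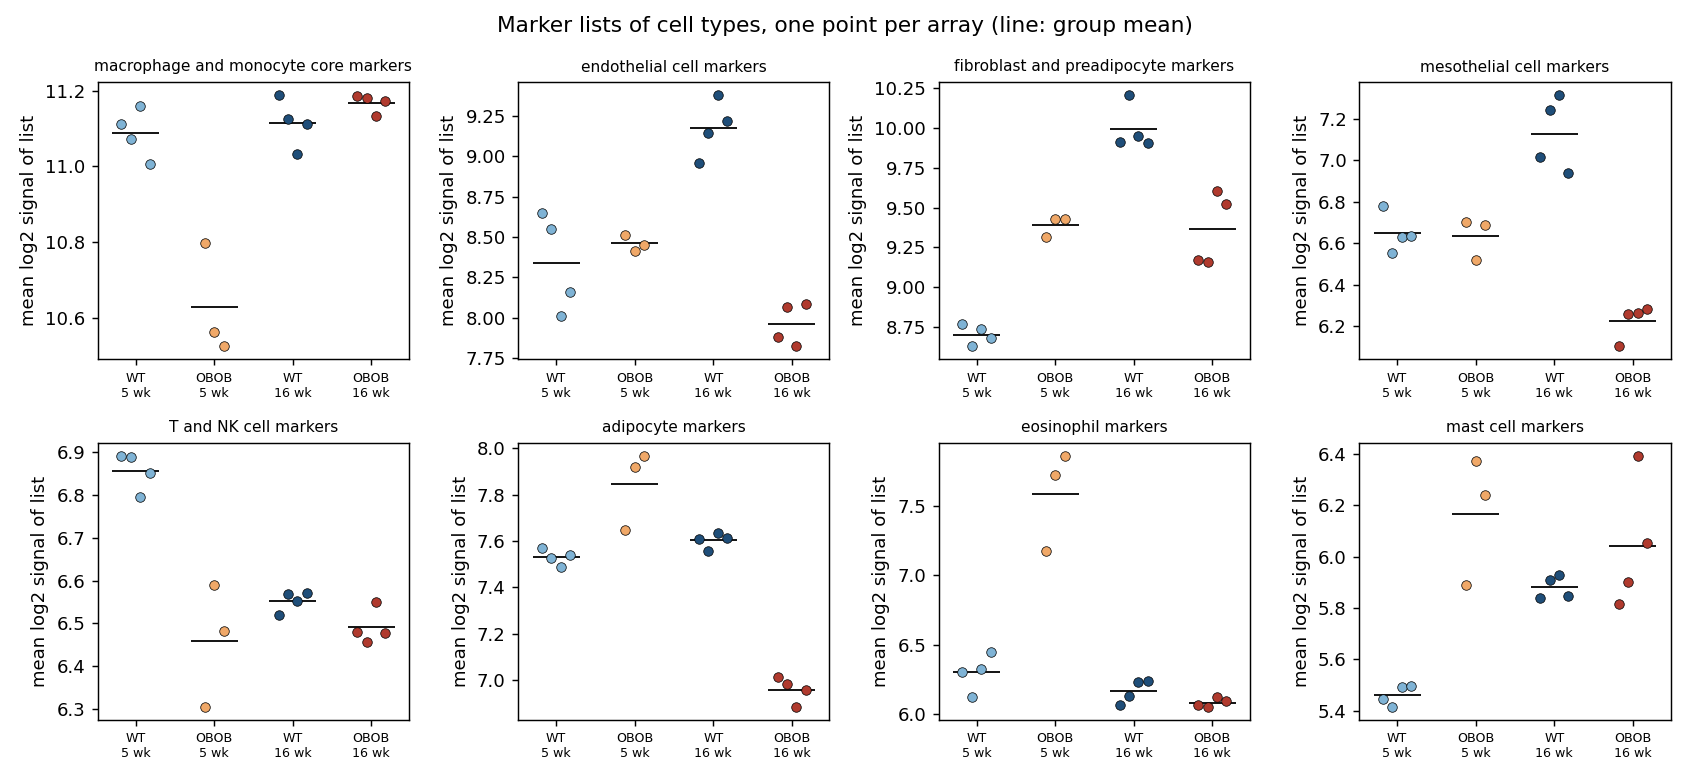
Mean log2 signal of 8 marker lists (y axes) in each of the 15 arrays by group, with the group mean as a line. Endothelial, fibroblast, mesothelial and adipocyte markers are lower in OBOB than in WT at 16 weeks, and eosinophil markers are higher in OBOB than in WT at 5 weeks.

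The genotype effects at the 2 time points shared many genes. Of the 2268 genes that passed at both, 1830 (80.7%) went the same way: 1169 were higher at both against 346 that independent lists would share, and 661 were lower at both against 260. Opposite directions were seen for 438 genes, 303 higher at 5 weeks and lower at 16 against 283 for independent lists, and 135 the other way against 319. Gpnmb, Tm4sf19, Atp6v0d2, Adam8, Lpl, Trem2, Itgax and Tnf rose at both, and Pla2g2d, Sult1e1, Cd163, Clec10a and Timd4 fell at both. Rnase2a and Retnlg, both higher at 5 weeks, were lower at 16 weeks, Retnlg by -1.34 on the log2 scale. Across the 19938 genes the log2 differences at the 2 time points correlated with Pearson r = 0.347 and Spearman rho = 0.287, where genes are not independent replicates. The 2 effects share no arrays.

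**Figure D5:**
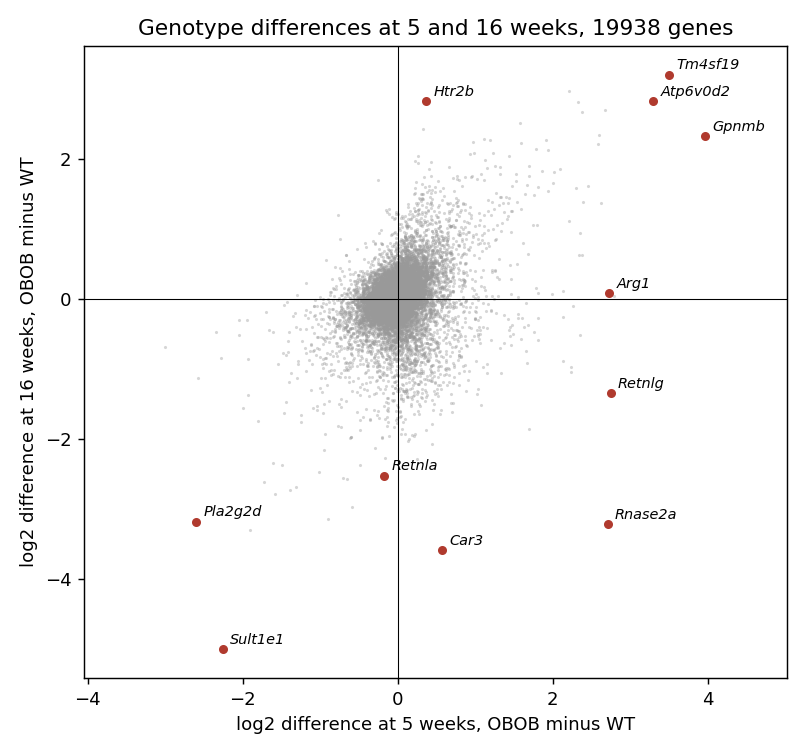
Log2 difference between OBOB and WT at 5 weeks (x axis) against that at 16 weeks (y axis), 1 point for each of 19938 genes, with selected genes labelled. Pla2g2d and Sult1e1 lie low at both time points, and Rnase2a, Retnlg and Arg1 rose at 5 weeks only.

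Tested directly, the genotype effect differed between 5 and 16 weeks in both directions. The difference of the 2 effects, 16 minus 5 weeks, was -5.92 ± 0.28 (SE) for Rnase2a, -4.15 ± 0.23 for Car3, -4.09 ± 0.23 for Retnlg, -3.54 ± 0.79 for an immunoglobulin kappa variable segment and -3.27 ± 0.25 for coagulation factor F5, with adjusted p between 6.97e-09 and 0.00393. It was 2.46 ± 0.19 for Htr2b, 2.10 ± 0.11 for the myosin Myh15, 1.97 ± 0.18 for the prostaglandin D synthase Hpgds, 1.96 ± 0.25 for the Fc receptor Fcgr4 and 1.78 ± 0.28 for the stromelysin Mmp3 (adjusted p between 1.34e-08 and 0.000229). Arg1 (-2.64 ± 0.17, adjusted p = 1.31e-07) and Retnla (-2.35 ± 0.16, adjusted p = 1.51e-07) moved down together, Arg1 by losing its rise and Retnla by falling at 16 weeks. The effects on Lpl (-0.03 ± 0.09, adjusted p = 0.886), Tnf (0.07 ± 0.17, adjusted p = 0.833), Clec10a (0.01 ± 0.15, adjusted p = 0.966), Cd36 (-0.10 ± 0.09, adjusted p = 0.533) and Plin2 (0.16 ± 0.16, adjusted p = 0.579) were not shown to differ. The effect on Gpnmb shrank (-1.64 ± 0.23) and those on Trem2 (1.02 ± 0.14), Itgax (0.71 ± 0.13) and Il10 (0.84 ± 0.18) grew, while that on Il6 went down (-1.56 ± 0.23). The effect on Adgre1 (0.86 ± 0.08) went from -0.17 at 5 weeks, which passed only in some settings (adjusted p from 0.0196 to 0.226), to a rise at 16 weeks. At least 1 group lay below the olfactory receptor level for Rnase2a, Htr2b, Myh15, Mmp3, Il6 and the immunoglobulin segment, so the size of their difference is not exact.

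By lists, cell cycle genes had a higher genotype effect at 16 than at 5 weeks in 32 of 35 (35 adjusted over the list alone), with Bub1 at 1.46 (median 0.79, adjusted p = 9.71e-25, and adjusted p = 0.036 with an estimated correlation). Adipocyte markers had a lower effect in 14 of 20 (16 adjusted over the list alone) (adjusted p = 3.09e-13, and adjusted p = 0.036 with an estimated correlation). Adipoq stood at -1.85, a size that is not exact because OBOB at 16 weeks lay below the olfactory receptor level. Endothelial (19 of 20, with Kdr at -2.14), fibroblast (17 of 18), mesothelial (10 of 15) and mural markers (8 of 12) were all lower, at adjusted p = 4.09e-21, adjusted p = 1.02e-20, adjusted p = 2.85e-10 and adjusted p = 2.4e-09. With an estimated correlation these 4 lists had adjusted p = 0.079, adjusted p = 0.064, adjusted p = 0.064 and adjusted p = 0.079, and adjusted over each list alone 19, 17, 11 and 10 genes were lower. Matrix genes were lower in 25 of 31 and higher in 1 (27 and 1 adjusted over the list alone), with Thbs1 at -2.75 (adjusted p = 1.53e-24, but adjusted p = 0.064 with an estimated correlation). Eosinophil markers were lower in 7 of 9 (7 adjusted over the list alone), with Alox15 at -3.20 (adjusted p = 9.2e-08, but adjusted p = 0.079 with an estimated correlation). Core macrophage markers were higher in 15 of 19 (17 and 1 lower adjusted over the list alone; adjusted p = 1.98e-09, but adjusted p = 0.1 with an estimated correlation). The alternative (M2) list was lower in 14 of 26 and higher in 4 (15 and 6 adjusted over the list alone; adjusted p = 2.16e-06, but adjusted p = 0.2 with an estimated correlation). Lipid-associated macrophage genes were not shown to differ as a list (adjusted p = 0.898). In all, 3642 genes passed the test of the difference, 1948 with a higher and 1694 with a lower effect at 16 weeks, and 645 by at least 2-fold.

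In WT, age was accompanied by a rise of stromal genes. From 5 to 16 weeks Abca8a rose 9.95-fold, Inmt 9.29-fold, the hyaluronan-binding protein Tnfaip6 8.85-fold, the sodium channel Scn7a 8.58-fold and the dipeptidase Dpep1 8.32-fold, with adjusted p between 7.36e-10 and 9.44e-09. Fibroblast markers rose in 15 of 18, also adjusted over the list alone, with Pdgfra 5.54-fold and Dpt 4.53-fold higher (adjusted p = 3.05e-15, but adjusted p = 0.12 with an estimated correlation). Matrix genes rose in 27 of 31, also adjusted over the list alone, with Dcn 4.05-fold and Lum 3.87-fold higher (adjusted p = 8.02e-20, but adjusted p = 0.12 with an estimated correlation). Endothelial markers rose in 19 of 20, also adjusted over the list alone, with Tek 2.37-fold higher (adjusted p = 4.75e-12, but adjusted p = 0.23 with an estimated correlation). Cell cycle genes fell in 32 of 35, also adjusted over the list alone, with Mki67 2.52-fold and Top2a 2.00-fold lower (median -0.59, adjusted p = 2.5e-18, but adjusted p = 0.085 with an estimated correlation). Oxidative stress genes rose in 22 of 25, also adjusted over the list alone, with Gpx3 3.40-fold and the metallothionein Mt2 2.86-fold higher (adjusted p = 2.15e-11, but adjusted p = 0.085 with an estimated correlation). Lysosomal genes rose in 16 of 30 and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 5.46e-07, but adjusted p = 0.26 with an estimated correlation). Lipid-associated macrophage genes rose in 17 of 25 and fell in none, also adjusted over the list alone (adjusted p = 7.09e-10, but adjusted p = 0.14 with an estimated correlation). Immediate early and dissociation response genes, which respond to tissue handling, rose in 14 of 24 and fell in none (15 adjusted over the list alone; median 0.28, adjusted p = 6.57e-05, but adjusted p = 0.19 with an estimated correlation). Gpnmb rose 5.26-fold, Il6 at least 4.41-fold (from 5.39, below the olfactory receptor level), the chemokine Cxcl13 6.54-fold and Tnf 1.85-fold, and Oas2 fell 2.69-fold.

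Among genes whose arrays did not overlap between the ages, the largest falls in WT were 7.36-fold for Spink11, 5.76-fold for Lcn5, 5.53-fold for Pate6, 5.07-fold for Spink8 and 4.37-fold for Rnase9. These are genes of the epididymis, the duct that lies beside the male fat pad. For Spink11, Pate6 and Rnase9 these folds are lower bounds, since WT at 16 weeks lay below the olfactory receptor level. A list of 7 epididymis genes picked after the values were seen lay at 7.61 ± 1.21 (SD, n = 4) in WT at 5 weeks, 5.97 ± 1.36 (SD, n = 3) in OBOB at 5 weeks, 5.10 ± 0.68 (SD, n = 4) in WT at 16 weeks and 4.83 ± 0.30 (SD, n = 4) in OBOB at 16 weeks. In all, 6167 genes passed between the 2 ages in WT, 3545 higher and 2622 lower at 16 weeks, 397 of them by at least 2-fold. With each array centred on its median, which moved the median of all genes from -0.03 to 0.07, the split was 5324 higher and 1126 lower. With the epididymis list as a covariate, chosen after seeing the data, 3724 genes passed, 3385 of them among the 6167. None of the 5 falls passed with it, which for Spink11, Lcn5 and Rnase9 follows from their being members of that list.

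In OBOB, lysosomal and lipid-associated macrophage genes rose with age as they did in WT, core macrophage genes rose, and adipocyte and eosinophil genes fell. From 5 to 16 weeks Htr2b rose 6.65-fold, the complement receptor Vsig4 5.48-fold, Cxcl10 4.59-fold, Pcp4l1 4.48-fold and Myh15 4.15-fold. Rnase2a fell 52.2-fold, Car3 25-fold, Retnlg 19.6-fold, Alox15 13.5-fold and F5 10.7-fold, and adjusted p for these 10 genes lay between 7.66e-11 and 2.12e-07. The folds of Htr2b, Myh15 and Rnase2a are lower bounds, since their lower group lay below the olfactory receptor level. Arg1 fell 6.28-fold and Retnla 4.28-fold, while Il10 rose 2.52-fold, Trem2 2.16-fold, Adgre1 1.95-fold, Tnf 1.95-fold and Itgax 1.89-fold. Lysosomal genes rose in 28 of 30, also adjusted over the list alone, with Ctsk 2.97-fold higher (adjusted p = 5.91e-18, but adjusted p = 0.2 with an estimated correlation). Core macrophage markers rose in 16 of 19 and fell in 1 (17 and 1 adjusted over the list alone), with Lyz1 2.18-fold higher (adjusted p = 1.26e-08, but adjusted p = 0.2 with an estimated correlation). Lipid-associated macrophage genes rose in 19 of 25 and fell in 2 (20 and 2 adjusted over the list alone; adjusted p = 1.26e-08, but adjusted p = 0.2 with an estimated correlation). Immediate early and dissociation response genes rose in 12 of 24 and fell in 2 (14 and 3 adjusted over the list alone; median 0.27, adjusted p = 0.00225, but adjusted p = 0.32 with an estimated correlation). That call was also lost with quantile normalization (0.17, adjusted p = 0.243, in a range from 7.31e-05 to 0.243 over the settings fixed in advance other than the estimated correlation). Adipocyte markers fell in 14 of 20 and rose in 1 (15 and 1 adjusted over the list alone), with Adipoq at least 5.70-fold (to 4.87, below the olfactory receptor level) and Plin1 3.53-fold lower (adjusted p = 9.23e-09, but adjusted p = 0.13 with an estimated correlation). Eosinophil markers fell in 7 of 9, also adjusted over the list alone, with Il5ra at least 5.25-fold lower (to 4.31) (adjusted p = 3.11e-08, but adjusted p = 0.2 with an estimated correlation). Endothelial markers fell in 12 of 20 (14 adjusted over the list alone), with Kdr 2.23-fold lower (adjusted p = 2.88e-06, but adjusted p = 0.4 with an estimated correlation). In all, 6293 genes passed, 4069 higher and 2224 lower at 16 weeks, 270 of them by at least 2-fold, and with each array centred on its median the split was 5570 higher and 1280 lower.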

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

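Tests chosen only after the results were seen were the comparison of endothelial with other immune cell markers, that of alternative (M2) with stromal markers, the neutrophil test, the relabelling used for the interaction, and the stromal and epididymis covariates.

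In some groups 1 array lay far from the others of its group. The ratio of its gap to the group's range (Dixon's test, groups of 4) passed for 19 of 414 gene groups and 5 of 138 list groups, and chance alone gives about 1 in 20. In WT at 16 weeks, replicate 2 was highest for Dpt (0.836), Gpx3 (0.892) and Sult1e1 (0.849) and for fibroblast and preadipocyte markers (0.854), replicate 3 highest for Rnase2a (0.880), replicate 4 lowest for Dhrs9 (0.847), and replicate 1 lowest for Tek (0.864) and highest for cytosolic ribosomal proteins (0.859). In OBOB at 16 weeks, replicate 1 was lowest for Itgam (0.954), Upk3b (0.914), mesothelial cell markers (0.854) and cholesterol efflux and LXR targets (0.961), and highest for Rnase2a (0.917) and Thrsp (0.838). Replicate 2 of that group was highest for Mki67 (0.919), replicate 3 lowest for Gla (0.868) and Slc16a3 (0.929), and replicate 4 highest for Il7r (0.955), Plin2 (0.835) and lysosome and vacuolar proton pump genes (0.931). In WT at 5 weeks, replicate 4 was highest for Cpa3 (0.851) and Msmo1 (0.885), replicate 1 lowest for Hpgds (0.837) and replicate 3 lowest for Pate6 (0.879).

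The genotype effect differed between 5 and 16 weeks, by the test of the interaction, for 84 of 114 named genes (log2 difference of the effects, 16 minus 5 weeks). Over all 19938 genes the share was 18.3%. Many of the 114 were named for a large genotype effect or a large difference in these same data, so their higher share follows partly from that choice. Among macrophage genes the genotype effect went up for Adgre1 (0.86), Aif1 (0.91), Cd68 (0.46), Cx3cr1 (1.54), Fcgr4 (1.96), Fcrls (0.57), Itgax (0.71), Mrc1 (0.56), Trem2 (1.02), Tlr13 (1.0), Slc37a2 (0.87), Slc40a1 (1.08), Abca1 (0.48), Il10 (0.84), Il7r (0.30), Dhrs9 (0.76), Htr2b (2.46) and Hpgds (1.97). It also went up for Cxcl10 (1.01), Ifit3 (0.65), Rtp4 (0.76), Gzma (0.71), Nkg7 (1.12), Mmp3 (1.78), Myh15 (2.10), Zranb3 (0.95), and for Bub1 (1.46), Kif11 (1.41), Top2a (1.26) and Tpx2 (1.0) of the cell cycle. Macrophage and cytokine genes whose effect went down were Arg1 (-2.64), Retnla (-2.35), Ccl24 (-0.73), Cd209d (-1.91), Cd209g (-1.37), Timd4 (-0.89), Clec4e (-0.83), Gpnmb (-1.64), Il1a (-1.36), Il6 (-1.56), Nos2 (-0.74), Ptgs2 (-1.71), Thbs1 (-2.75), Vegfa (-1.61), Mmp12 (-1.0), Mmp19 (-1.25), Mmp9 (-2.37), Olr1 (-2.37), Vldlr (-1.71), Slc16a3 (-1.92), Slc7a11 (-2.01), Srxn1 (-0.80) and F10 (-1.09). Adipocyte genes with a lower effect were Adipoq (-1.85), Aqp7 (-1.77), Car3 (-4.15), Cyp2e1 (-1.21), Mgll (-1.86), Pparg (-0.41), Scd1 (-2.19) and Thrsp (-1.74). For Pparg this was a smaller rise in OBOB at 16 than at 5 weeks, not a fall. Stromal and vascular genes with a lower effect were Cd34 (-1.84), Clec3b (-1.70), Gpihbp1 (-1.77), Gpm6a (-1.39), Inmt (-1.38), Kdr (-2.14), Lum (-1.03), Myl9 (-1.28), Penk (-2.24), Rbp7 (-1.57), Rgs5 (-2.19), Sult1e1 (-2.75) and Upk3b (-2.02). Other leukocyte genes with a lower effect were Alox15 (-3.20), Ccr3 (-1.75), Cpa3 (-1.70), Mcpt4 (-1.71), Rnase2a (-5.92), Retnlg (-4.09), S100a9 (-1.31), Bank1 (-0.97), F5 (-3.27) and an immunoglobulin kappa variable segment (-3.54). The sizes for Adipoq, Cyp2e1, Htr2b, Il6, Mmp3, Myh15, Rnase2a and the immunoglobulin segment are not exact, since at least 1 of their groups lay below the olfactory receptor level. The call of Pparg was lost without WT at 5 weeks replicate 4 (-0.38), OBOB at 5 weeks replicates 1 (-0.41) or 2 (-0.39), WT at 16 weeks replicates 2 (-0.40), 3 (-0.41) or 4 (-0.39), or OBOB at 16 weeks replicate 3 (-0.39). With the replicate number as a block Pparg (-0.38) and Abca1 (0.48) no longer passed, with adjusted p between 0.00329 and 0.0693 for Pparg and between 0.000947 and 0.0592 for Abca1 over the settings fixed in advance.

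By the same test 31 lists differed in their genotype effect between the time points, given as the median log2 difference. With an estimated correlation only cell cycle genes and adipocyte markers passed, 2 of the 31 (adjusted p = 0.036 for each). The effect went up for cell cycle (0.79), inflammasome and pattern recognition (0.59), core macrophage and monocyte (0.56), lysosome and proton pump (0.33), T and NK cell (0.29), interferon-stimulated (0.27) and autophagy genes (0.13). It went down for eosinophil (-1.70), endothelial (-1.38), fibroblast (-1.28), mural and smooth muscle (-1.09), adipocyte (-0.94) and mesothelial markers (-0.84), extracellular matrix genes (-1.17) and PPAR gamma targets (-0.88). Smaller declines were those of alternative (M2) markers (-0.57), monocyte and recruited macrophage (-0.47), dendritic (-0.41), neutrophil (-0.33), mast cell (-0.24) and B and plasma cell markers (-0.24), and of erythroid and platelet genes (-0.09). Metabolic and stress lists with a lower effect were fatty acid synthesis (-0.39), eicosanoid metabolism (-0.31), hypoxia (-0.30), NRF2 and oxidative stress (-0.22), glycolysis (-0.18), triglyceride synthesis (-0.17), cytosolic ribosomal proteins (-0.14), fatty acid uptake (-0.11) and lipid droplet proteins (-0.06). Calls were lost without OBOB at 5 weeks replicate 3 for interferon-stimulated (0.21), autophagy (0.13) and erythroid genes (-0.04), without OBOB at 5 weeks replicate 2 for triglyceride synthesis (-0.14), and for autophagy also without WT at 5 weeks replicate 3 (0.14) or WT at 16 weeks replicates 1 (0.14), 3 (0.13) or 4 (0.13). They were also lost with quantile normalization for triglyceride synthesis (-0.19), without the dimmest genes for autophagy (0.13), and with fry for cytosolic ribosomal proteins (-0.14, adjusted p = 0.143, in a range from 0.000317 to 0.143 over the settings fixed in advance other than the estimated correlation).

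Probe sets left out of the gene results for want of a single symbol also carried the genotype effect. Of 13767 such probe sets 1051 passed at 5 weeks and 1608 at 16 weeks, adjusted over all 35556 probe sets of the table. What they measure was not examined.

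Lower stromal and alternative (M2) markers in OBOB were weighed first. A larger share of macrophages would lower every other cell type alike, and this stays open: at 16 weeks the median of 20 endothelial markers was -1.248 and that of 27 other immune cell markers, all at least 2 log2 units above the olfactory receptor level in WT, -0.467, a gap of -0.781 that is smaller than the SD of 0.889 between the latter. A two-sided permutation of genes between the 2 sets gave p = 0.0018. It treats genes as independent and does not measure the spread between arrays. Neutrophil (-1.342) and B and plasma cell markers (-0.956) fell about as far as endothelial ones, whereas dendritic (-0.496), T and NK (-0.329) and eosinophil markers (-0.162) moved less and mast cell markers stood at 0.168. Fewer stromal cells would not explain the M2 list at 5 weeks, whose median was already -0.634 (-0.806 to -0.573 with 1 array left out) while 65 stromal markers stood at 0.144 (0.098 to 0.214), against -0.948 at 16 weeks. A smaller stromal share of the isolate at 16 weeks, from the isolation or from the tissue, also stays open, as do genotype itself and, at 5 weeks, a loss of macrophage signal, since core macrophage markers fell there almost as far (-0.59, 13 of 19 lower). Such a loss did not reach every macrophage list: lipid-associated macrophage genes rose from 9.324 ± 0.126 (SD, n = 4) to 10.584 ± 0.070 (SD, n = 3). Cd163 stands in both the M2 and the core list.

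Higher eosinophil markers in OBOB at 5 weeks may come from eosinophils or basophils among the isolated cells, or from macrophages expressing these genes. A second list of 10 eosinophil and basophil genes, of which 1 (Cebpe) also stands in the neutrophil list, had a median of 0.193 with 4 higher and none lower (one-sided permutation p = 0.00051), too small a shift to decide. In the first list 3 of 9 genes belong to other lists too, Ccr3 (7.26 to 9.64) and Alox15 (9.12 to 11.36) rose well above the olfactory receptor level of 5.43, and the granule genes Epx (5.33 ± 0.06 in WT, 5.35 ± 0.10 in OBOB) and Prg2 (5.34 ± 0.26 and 5.38 ± 0.20), singled out after their values were seen, stayed at that level. Neutrophils were argued against by a median of -0.028 for their markers, 1.499 below the eosinophil list (p = 0.002 by permutation of genes), although Retnlg rose. Both p-values treat genes as independent and do not measure the spread between arrays. Whether genotype changed the eosinophils or the macrophages was not tested, and no sort or gate is named in the labels.

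Epididymis genes were high in some arrays, most in WT at 5 weeks, where Gpx5 lay at 8.83 ± 1.72 (SD, n = 4) and the mean of the 7 genes ran from 5.866 to 8.620 between arrays. If pieces of epididymis were carried over with the fat pad, other epididymis genes should vary with them inside each group. For a second list of 14, none of them in a fixed list, the median correlation of deviations from the group means was 0.505, just over the bound of 0.5 set for it, with 7 genes above that bound and a range from -0.084 to 0.799, against a 95th percentile of 0.158 for 10000 random lists. This is consistent with carry-over, which would make the falls of these genes with age in WT, and part of their difference at 5 weeks, a matter of dissection. An effect of age or genotype on these genes within the fat was not tested.

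Regrouping the arrays asked whether other groupings gave as many genes, and in each comparison the real one gave the most. This cannot exclude chance, since 1 of 35 is the lowest share that 35 splits allow. Splits that mix groups also widen the spread within them, which tends to lower their counts. Nor can regrouping tell whether arrays share animals. For the genotype effect at 5 weeks 1 of 35 splits, the real one, gave as many genes (3887, highest other 1507), as did 1 of 35 for the genotype effect at 16 weeks (6193, highest other 0), 1 of 35 for age in WT (6167, highest other 1) and 1 of 35 for age in OBOB (6293, highest other 2733). For the interaction the genotype effect shared by both time points was first removed from each gene. Of 100 drawn relabellings 1, the real one, then gave 3642 genes (highest other 3). With that shared effect left in, as first planned, the highest other was 3468, because unequal relabelling turns a shared effect into a difference between the time points.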

How the results depend on the processing

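The stromal and epididymis covariates were chosen only after the results were seen, and all other settings were fixed in advance. Of 277 single-gene results 234 had passed, while 18 of the 43 that had not passed did so in at least 1 setting. Of the 234, 226 passed in every setting fixed in advance that was tried on single genes. Apart from index genes, they were named as the largest changes or the leading list members that passed, which favours keeping a call. The minimum log2 change of 1 was not tried on them, and a gene removed with the dimmest genes was not counted as lost. Of 138 list results that passed, 108 did so in every setting fixed in advance other than the estimated correlation, which left 5, 1, 2, 0 and 0 lists for the genotype effects at 5 and 16 weeks, the interaction and age in WT and in OBOB (25, 25, 31, 30 and 27 with the preset value). The fall of the alternative (M2) list (medians -0.634 and -0.705) was among those lost with it (adjusted p = 0.27 and adjusted p = 0.21), because the spread attributed to a list grows with the correlation of its genes. The M2 fall passed in every other setting, with medians from -0.806 to -0.573 at 5 weeks and from -0.742 to -0.681 at 16 weeks when 1 array was left out. The classical (M1) list passed at 5 weeks with the stromal covariate (0.168, adjusted p = 0.0238). Over the settings fixed in advance other than the estimated correlation, with which it did not pass either, its adjusted p ran from 0.0656 to 0.382. At 16 weeks the list passed with fry, whose test is of the genes' mean direction, at a median of -0.001 (adjusted p = 0.0272, the lowest of a range up to 0.736 over the same settings). Its medians ran from 0.123 to 0.179 and from -0.069 to 0.054 with 1 array left out, and the cause of these changes was not tested.

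A minimum of 2-fold left 266, 619, 645, 397 and 270 genes in the order above, by its construction. Leaving out 1 array gave 2899 to 3626, 5416 to 5831, 3184 to 3637, 5037 to 5920 and 5275 to 5787 genes, and 23 to 29, 24 to 26, 28 to 33, 28 to 31 and 25 to 27 lists. With the replicate number as a block 2996, 5616, 2904, 5484 and 5315 genes passed. Deviations of arrays with the same number correlated between -0.134 and 0.105, and those with different numbers between -0.124 and 0.157. These values gave no sign that the numbers pair arrays, but so few arrays cannot exclude it. The stromal covariate left 2246 genes at 5 weeks and 232 at 16 weeks, where it nearly repeats genotype and the median SE grew from 0.082 to 0.291, with 83.6% of the genes that had passed keeping their sign. At 16 weeks it reversed fatty acid synthesis and desaturation (0.016), extracellular matrix (0.338), endothelial (0.164) and mural markers (0.241), Rbp7 (0.066), Myl9 (0.240), Rgs5 (0.313) and Cd34 (0.008), several of which belong to the covariate itself. The epididymis covariate left 3724 genes for age in WT, where it reversed Lcn5 (0.145), a member of the covariate, and 2820 for the genotype effect at 5 weeks. Centring on the array median moved the median of triglyceride synthesis genes for age in OBOB to 0.010, by shifting all genes. The overlap of the genotype effects was 1824 genes in the same and 450 in opposite directions after quantile normalization, and 2079 and 536 without the dimmest genes. Between 4.3% and 7.54% of the genes that passed lay at or below the olfactory receptor level in the groups compared, where signal cannot be told from background by these values.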

Other observations

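Every list in this part was fixed in advance, and only the stromal covariate was chosen after results were seen. Some lists of energy metabolism were higher in OBOB, but fatty acid beta-oxidation did not pass at 5 weeks (3 higher and 1 lower of 24, adjusted p = 0.292) or 16 weeks (8 and 2, adjusted p = 0.151), with the same counts adjusted over the list alone. Oxidative phosphorylation and TCA cycle genes counted 16 higher and 1 lower of 36 at 5 weeks, the same adjusted over the list alone (median 0.15, adjusted p = 4.32e-08, and adjusted p = 0.27 with an estimated correlation). At 16 weeks 18 were higher and 1 lower (20 and 2 adjusted over the list alone; median 0.21, adjusted p = 0.00132, and adjusted p = 0.53 with an estimated correlation). Of 21 cholesterol synthesis genes 11 rose and 1 fell at 16 weeks, also adjusted over the list alone, with Msmo1 2.04-fold higher (adjusted p = 0.00164, and adjusted p = 0.22 with an estimated correlation). Glycolysis genes rose in 10 of 19 and fell in 1 at 16 weeks (10 and 3 adjusted over the list alone), with Pgam1 1.99-fold higher (adjusted p = 0.00236, and adjusted p = 0.22 with an estimated correlation). Cell cycle genes were already higher at 5 weeks in 15 of 35 (24 adjusted over the list alone), with Tpx2 1.46-fold higher (median 0.25, adjusted p = 6.26e-09, and adjusted p = 0.11 with an estimated correlation).

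Antigen presentation genes of MHC class II fell in 8 of 12 and rose in 2 at 16 weeks, also adjusted over the list alone (median -0.29, adjusted p = 0.013, and adjusted p = 0.35 with an estimated correlation). At 5 weeks 6 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.21, adjusted p = 0.0257, and adjusted p = 0.35 with an estimated correlation), a call also lost without OBOB replicate 1 (median -0.17, adjusted p = 0.114, in a range from 0.00152 to 0.114 over the settings fixed in advance other than that correlation). Inflammasome genes, which rose at 16 weeks, fell in 12 of 26 and rose in 4 at 5 weeks (13 and 4 adjusted over the list alone; median -0.27, adjusted p = 0.0164, and adjusted p = 0.35 with an estimated correlation). That call was also lost without OBOB replicate 3 (-0.18, adjusted p = 0.0548, in a range from 0.00222 to 0.0548 over the settings fixed in advance other than the estimated correlation), and Il1rn went against it, 6.04-fold higher. Both calls at 5 weeks were also lost with the stromal marker mean as a covariate, at -0.17 for MHC class II (adjusted p = 0.0995) and -0.18 for the inflammasome list (adjusted p = 0.307). With age, complement genes rose in 11 of 16 in WT (12 adjusted over the list alone; adjusted p = 5.44e-07, and adjusted p = 0.14 with an estimated correlation), and in OBOB 12 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000119, and adjusted p = 0.22 with an estimated correlation). Cholesterol synthesis genes rose with age in WT in 16 of 21, also adjusted over the list alone, with Msmo1 1.85-fold higher (median 0.49, adjusted p = 1.29e-08, and adjusted p = 0.085 with an estimated correlation). Genes of the unfolded protein response rose in 16 of 27 and fell in 1 with age in WT (17 and 1 adjusted over the list alone; adjusted p = 1.6e-05, and adjusted p = 0.14 with an estimated correlation).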
